A study of Homo sapiens with 8 samples.

How the data were processed

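Total RNA from 2 human breast cancer cell lines, ZR75-1 (ER-positive per the labels) and SKBR3 (ER-negative per the labels), was measured on 8 Affymetrix HG-Focus arrays. Each line had 2 arrays of cells transfected with a plasmid carrying HSD17B14 and 2 arrays of cells given the same amount of vector without the insert. Per the labels' protocols, cells grew in phenol-red free medium with 4% fetal bovine serum, were transfected with FuGene-6 at 24 h after seeding and were harvested 48 h after transfection. RNA was prepared with Trizol, cleaned on columns and examined on a Bioanalyzer, and 5 ug was biotin-labelled. The labels speak of duplicates without saying whether these were separate cultures, so p-values measure only the spread between arrays of a group.

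The values used were the deposited signal intensities, 1 per probe set and array, on a linear scale. They were made with MAS5, per the submitters' processing notes, with no version given. The values themselves show that every array has a mean of 100.1 after the highest and lowest 2% of probe sets are removed. The table holds 8793 probe sets, of which 47 are Affymetrix controls and were left out of the tests. Of the other 8746, 7840 carry 1 gene symbol in the platform annotation, 388 carry several and 518 carry none here. The gene ID of 7838 matched the gene name table, which changed 0 symbols. No gene was named from a probe set with several symbols. The file gives no detection calls. As on any array, precision is limited by the number of arrays.

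Values below 1, which made up 2.41% to 7.13% of an array, were raised to 1 and log2 was taken. The median log2 signal per array ran from 4.392 to 4.755, a gap of 0.36 that lies under the 0.5 set for re-centring, so the scaling was kept as deposited. A probe set was tested if it lay above the array's own 40th percentile (12.1 to 17.6 in signal) on at least 2 arrays, which left 6251 probe sets and 5552 named genes. limma 3.58.1 in R 4.3.3 fitted the 4 group means with eBayes and a mean-dependent prior (4 residual and 7.39 prior degrees of freedom, median SD 0.36 on the log2 scale). The contrasts were the plasmid's effect in each line, its mean over both lines, the difference of the effects (ZR75-1 minus SKBR3) and ZR75-1 minus SKBR3 in the vector controls. A call needed a Benjamini-Hochberg adjusted p under 0.05, and errors given after a log2 value are limma's standard errors with n = 2 arrays per group, or n = 4 per arm for the averaged effect. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

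Gene lists on steroid biology, cell cycle, stress and interferon responses, metabolism and cell type markers were fixed at the outset, as were the model, the filter and the rule for naming genes. Of these, 26 had at least 5 tested genes and entered camera with a preset correlation of 0.01, with adjustment over all lists of a contrast. Camera with an estimated correlation and fry were run beside it. The estimate was 0.57 for ribosomal protein and 0.23 for oxidative phosphorylation genes. After rounding it was 0.01 for G2/M, -0.03 for fatty acid metabolism and -0.04 for histone genes, no higher than the preset. Where these last 3 lists did not pass with it, a higher correlation between genes is not the reason. A gene was represented by its probe set with the highest mean log2 value. The rule named the HSD17B family, ESR1, PGR, TFF1, GREB1 and ERBB2, and some further items are not reported here. It also took, per contrast, the 10 largest changes in each direction among genes past the threshold with no overlap between the arrays of the groups, filled up with the smallest p-values and said not to pass where fewer passed. From each list described it took up to 4 members with the largest absolute moderated t.

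Where all arrays of a group lay under a common floor of 17.6, the highest of the arrays' 40th percentiles, a fold is a lower bound against that floor, and no fold is given where both groups lay under it or the bound is 1. This floor was chosen after seeing the data. Alternatives written before the data were examined were quantile normalization, median centring, no filter, a 60th percentile filter, log2 of the value plus 32, a prior not dependent on the mean, the replicate number as a block, each line fitted alone, and leaving out each array. The prior not dependent on the mean is called "without the prior" below. It drops only the dependence on the mean. Raising values to the common floor, a block for the level of the Bacillus spike-in controls and the actin 3'/5' ratio as a covariate were added after seeing the data.

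The model was tested on simulated data, in 20 runs with 200 of 6251 probe sets changed. At a 1.5-fold change it recovered 2.69% of changed probe sets in ZR75-1, 3.51% in SKBR3, 16.2% for the averaged effect and 0.149% for the difference between lines. At 2-fold these shares were 21.3%, 24.6%, 40.7% and 5.15%, and at 4-fold 54%, 52.1%, 65.2% and 34.4%. The share of false calls was 6.59%, 3.97%, 5.47% and 4.55%. With no effect simulated, at most 0, 1, 2 and 0 probe sets and 0 of 26 lists were called. Probe sets were simulated independently of each other. These runs therefore cannot show how correlation between genes affects the calls or the list tests.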

Results

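HG-Focus arrays measured messenger RNA in ZR75-1 and SKBR3 cells 48 h after transfection with an HSD17B14 plasmid or with the empty vector, in 4 groups of 2 arrays. HSD17B14 encodes a member of the 17-beta-hydroxysteroid dehydrogenase family, enzymes that interconvert active and less active sex steroids. Log2 signals of arrays of the same group correlated across probe sets with Pearson's r of 0.915 for ZR75-1 with HSD17B14, 0.888 for ZR75-1 controls, 0.96 for SKBR3 with HSD17B14 and 0.899 for SKBR3 controls. Arrays of the same line but different groups correlated at values that overlap these, from 0.872 to 0.903 in ZR75-1 and from 0.894 to 0.948 in SKBR3, where control 1 stood apart from the other 3 arrays (0.894 to 0.899). Genes are not independent replicates, so these values describe the arrays only. The arrays labelled SKBR3 carried low ERBB2 signals, between 25.9 and 46.8, against 95.9 to 226 on the ZR75-1 arrays, and they are called SKBR3-labelled here. ERBB2 encodes HER2, the receptor whose gene SKBR3 cells are known to carry in amplified form.

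HSD17B14 itself followed the plasmid in both lines. In ZR75-1 the signals were 107.5 and 135.3 with the plasmid and 17.8 and 2.1 with the vector alone, a fitted log2 change of 4.30 ± 0.78 (adjusted p = 0.0296). The size of this change rests on the low control values, since it was 2.77 with values raised to the common floor and ran from 2.76 without control 2 to 5.84 without control 1. It did not pass when any 1 of the 4 HSD17B14 arrays of both lines was left out (adjusted p from 0.0706 to 0.113). In the SKBR3-labelled cells the signals were 650.7 and 743.6 against 2.0 and 4.2, at least 39.5-fold higher (adjusted p = 1.42e-04). The change did not pass as different between the lines (adjusted p = 0.21), and its size is not given since the SKBR3-labelled controls lay under the floor. The signals with the plasmid themselves did not overlap, at 650.7 and 743.6 in the SKBR3-labelled cells against 107.5 and 135.3 in ZR75-1. The probe set is of a kind that can bind related transcripts.

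**Figure D1:**
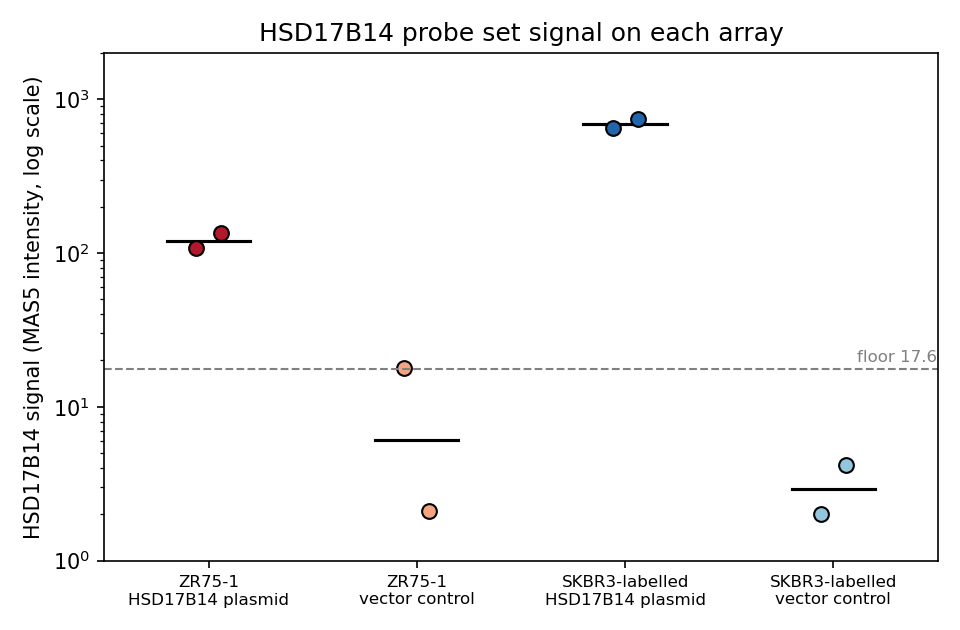
HSD17B14 signal per array on a log axis for the 4 groups of 2 arrays, with a horizontal line at each group's geometric mean and a dashed line at the common floor of 17.6. The plasmid arrays lie at 107.5 and 135.3 in ZR75-1 and at 650.7 and 743.6 in the SKBR3-labelled cells, and the control arrays at or under 17.8.

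The first comparison asks what the plasmid changed in the ER-positive line. In ZR75-1, UCP2, a mitochondrial carrier, fell 3.38-fold (log2 -1.76 ± 0.18, adjusted p = 0.00181). EPHX1, the microsomal epoxide hydrolase, fell 3.27-fold (-1.71 ± 0.24, adjusted p = 0.0109), and PLK1, a kinase of mitosis, fell 2.95-fold (-1.56 ± 0.23, adjusted p = 0.0124). Interferon-stimulated genes rose, among them the chemokine CXCL10 by 1.76 ± 0.22 (adjusted p = 0.00614) and IFI27 by 1.33 ± 0.16 (adjusted p = 0.00575) on the log2 scale. CFB, complement factor B, rose from signals of 4.5 and 20.2 to 98.8 and 66.3 (log2 3.09 ± 0.67, adjusted p = 0.0463). Of 6251 probe sets, 46 were higher and 49 lower, which stand for 44 and 45 named genes.

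Several of the largest rises in ZR75-1 started from signals under the common floor, and 6 of the 95 called probe sets lay under it in both groups. PTPRM, a receptor tyrosine phosphatase, was at least 2.72-fold higher (adjusted p = 0.0446) and PRR3 at least 1.11-fold higher (adjusted p = 0.0305). CST4, a salivary cystatin, went from 2.6 and 1.0 to 19.3 and 13, and the transcription factor ETS2 from 1.9 and 1.5 to 13.6 and 18.8, which allows no fold. CSRP2, CXCL2, HSD17B11 and SRPX passed the test with all 4 ZR75-1 signals under the floor, the highest being 16.4 for CSRP2. Among the lower genes, USF2, a transcription factor, was at least 2.61-fold lower (adjusted p = 0.0305) and the GTPase RAC2 at least 1.25-fold lower (adjusted p = 0.0484). PTOV1 fell from signals of 166.4 and 159.1 to 37.1 and 44.6 (adjusted p = 0.0304). The integrin subunit ITGA3 fell by 1.89 ± 0.40 on the log2 scale, and ARID1A, a subunit of a chromatin remodelling complex, by 1.84 ± 0.40 (adjusted p = 0.0449 and 0.0463). SATB1, an organiser of chromatin, had signals of 0.9 and 0.9 against 10.2 and 20.5, and ROR1 lay under the floor in both groups.

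Of 38 tested type I interferon response genes in ZR75-1, 9 rose, 0 fell and 29 did not pass, and 15 rose when adjusted over the list alone. The count of 9 was 2 and 5 without HSD17B14 arrays 1 and 2, and 4 without either control or either SKBR3-labelled HSD17B14 array. Besides CXCL10 and IFI27, the antiviral membrane proteins IFITM3 and IFITM1 rose by 1.11 ± 0.16 and 1.05 ± 0.13. The list's median log2 change was 0.43 (camera adjusted p = 2.21e-08), with adjusted p = 0.165 with an estimated correlation. The 28 tested proteasome genes had a median of 0.25, with 0 called by limma over all genes (11 higher at an unadjusted p under 0.05) and 11 higher when adjusted over the list alone (camera adjusted p = 1.11e-05, and adjusted p = 0.388 with an estimated correlation). Among those 11 were PSMD4 at 0.53 ± 0.13, PSMC6 at 0.66 ± 0.16, PSMA4 at 0.60 ± 0.15 and PSME1 at 0.48 ± 0.13. Of 40 oxidative phosphorylation genes, COX7A2, a subunit of cytochrome c oxidase, rose by 0.76 ± 0.16, and 3 were higher and 2 lower when adjusted over the list alone. That list's median was 0.23 (camera adjusted p = 0.0143, and adjusted p = 0.715 with an estimated correlation), and it did not pass after quantile normalization (0.18, adjusted p = 0.401).

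Other groups in ZR75-1 moved in part without a call for the list. Of 30 hypoxia and glycolysis genes, 3 fell, and 1 was higher and 4 lower when adjusted over the list alone (median -0.17, camera adjusted p = 0.52). The 3 were the glycolytic enzymes PKM at -1.18 ± 0.17, ENO2 at -1.15 ± 0.25 and TPI1 at -0.70 ± 0.13. Of 39 estrogen response genes, 1 fell, also when adjusted over the list alone (median -0.12, camera adjusted p = 0.575). It was IGFBP4, which binds insulin-like growth factors, at -1.51 ± 0.17, while CTSD at -0.98, FKBP4 at -0.52 and SERPINA3 at 0.81 did not pass. FASN, the fatty acid synthase, fell by 1.54 ± 0.26, the only called member of 26 fatty acid metabolism genes (1 higher and 2 lower when adjusted over the list alone, median -0.17, camera adjusted p = 0.52). Linker and core histones went both ways, with H1-2 at 0.93 ± 0.14, H2BC12 at 0.70 ± 0.15 and H1-10 at -1.0 ± 0.22. Of 21 histone genes 2 were higher and 1 lower, 3 and 1 adjusted over the list alone (median 0.17, camera adjusted p = 0.301). Among 35 G2/M genes, NDC80, a kinetochore protein, rose by 0.88 ± 0.17 and PLK1 fell (3 higher and 4 lower adjusted over the list alone, median -0.07, camera adjusted p = 0.975). In the NF-kB target list, IL6 rose by 1.81 ± 0.32 and CXCL2 passed from under the floor, 2 of 25 genes and also 2 when adjusted over the list alone. That list's median of -0.32 had the opposite sign to its mean of 0.05 and to the test's direction (camera adjusted p = 0.979). With median centring the medians of the glycolysis, estrogen response, fatty acid and G2/M lists turned to 0.03, 0.08, 0.04 and 0.14.

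The 3'/5' ratios of GAPDH and actin are measures of RNA integrity, and they went opposite ways in ZR75-1. The GAPDH ratio was 0.896 and 0.883 on the arrays with HSD17B14 and 1.084 and 1.039 on their controls. The actin 3'/5' ratio was 2.83 and 2.66 on the ZR75-1 arrays with HSD17B14 and 2.03 and 2.02 on their controls. With it as a covariate 1 probe set passed in ZR75-1, with the spike-in level as a block 19 passed, with median centring 23, and without HSD17B14 array 1 13. The balance of 46 higher and 49 lower turned both ways, to 57 and 20 without control 1, 31 and 12 without control 2, and 13 and 33 without HSD17B14 array 2.

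The second comparison puts the same question to the ER-negative, SKBR3-labelled cells. Interferon-stimulated genes rose there together. OAS1 and OAS2, synthases that respond to double-stranded RNA, rose 5.99-fold (log2 2.58 ± 0.16, adjusted p = 7.53e-06) and 5.74-fold (2.52 ± 0.24, adjusted p = 1.32e-04). CXCL10 rose 7.64-fold (2.93 ± 0.22, adjusted p = 3.48e-05) and TNFSF10, the death ligand TRAIL, rose 6.62-fold (2.73 ± 0.30, adjusted p = 3.91e-04). Of 6251 probe sets, 59 were higher and 3 lower, and 31 of the 56 higher genes belonged to the interferon list. At an unadjusted limma p under 0.05 the split was less uneven, with 310 higher and 239 lower. Of the 38 genes on that list, 31 rose, 0 fell and 7 did not pass, 35 rose when adjusted over the list alone, and the fitted change of all 38 was above 0. IFITM1 rose by 2.17 ± 0.13 and the antiviral GTPase MX1 by 1.89 ± 0.13. The list's median was 1.57 (camera adjusted p = 2.28e-89, and adjusted p = 0.00161 with an estimated correlation).

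The other large rises in the SKBR3-labelled cells started from control signals under the floor. CFB was at least 3.95-fold higher (adjusted p = 0.0306), S100A9, a calcium-binding protein of inflammation, at least 2.75-fold (adjusted p = 1.13e-04), LAMP3 at least 2.42-fold (adjusted p = 0.028), and the lectin LGALS9 at least 1.55-fold (adjusted p = 0.00608). IGFBP2 went from signals of 1.4 and 0.7 to 14.8 and 21.4, at least 1.01-fold (adjusted p = 1.29e-04). The 3 lower genes were ATF3, a stress-induced transcription factor, at 1.85-fold (-0.89 ± 0.17, adjusted p = 0.0285), CDC20 and ODC1. CDC20, an activator of the anaphase-promoting complex, fell 1.76-fold (-0.82 ± 0.15, adjusted p = 0.0268), and ODC1, which starts polyamine synthesis, 1.67-fold (-0.74 ± 0.13, adjusted p = 0.0201). These 3 did not pass with median centring, without either HSD17B14 array or without control 1 of these cells, and without control 2 the count of lower probe sets was 11. The next genes by p-value did not pass, and the closest, GUSBP14, was at least 1.24-fold lower (adjusted p = 0.0529). FDPS had a log2 change of -0.78 ± 0.16, CHP1 -0.63 ± 0.15, UBE2S -0.81 ± 0.20, CCT7 -0.60 ± 0.16 and RPL38 -0.71 ± 0.19, with adjusted p from 0.0542 to 0.183. ATN1 lay under the floor throughout.

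Among smaller groups in the SKBR3-labelled cells, NFKBIA, the inhibitor of NF-kB, rose by 0.78 ± 0.16, the 1 call among 25 NF-kB targets. When adjusted over the list alone 5 were higher, including IL6 at 1.39 ± 0.32 and CXCL1 at 2.16 ± 0.52 (median 0.43, camera adjusted p = 3.38e-04, and adjusted p = 0.0932 with an estimated correlation). Of 35 G2/M genes, CDC20 was the 1 that fell, also when adjusted over the list alone (median -0.26, camera adjusted p = 4.35e-06, and adjusted p = 0.0932 with an estimated correlation). AURKA at -0.48 ± 0.13 and PLK1 at -0.68 did not pass. The 42 ribosomal protein genes had a median of -0.33, with RPL32 at -0.63, RPL14 at -0.53 and RPL7 at -0.52. Of them 0 were called by limma, also when adjusted over the list alone, and 14 were lower at an unadjusted p under 0.05 (camera adjusted p = 9.38e-14, and adjusted p = 0.431 with an estimated correlation), and the median was -0.08 after quantile normalization. Of 21 histone genes 0 passed limma over all genes, 5 were higher at an unadjusted p under 0.05 and 2 when adjusted over the list alone, H2AC6 at 0.80 ± 0.17 and H2BC9 at 1.04 ± 0.25. Their list had a median of 0.27 (camera adjusted p = 0.0352, and adjusted p = 0.243 with an estimated correlation). The lists of 26 fatty acid metabolism and 40 oxidative phosphorylation genes had medians of -0.18 and -0.09 with 0 genes called by limma either way, and 4 and 3 lower at an unadjusted p under 0.05. Camera gave adjusted p = 0.0311 and 0.0343 (and adjusted p = 0.242 and 0.65 with an estimated correlation). Of 39 estrogen response genes, SERPINA3, a protease inhibitor, rose by 1.18 ± 0.23, and 2 were higher when adjusted over the list alone (median 0.13, camera adjusted p = 0.188). With median centring the histone, fatty acid and oxidative phosphorylation lists did not pass (camera adjusted p = 0.0933, 0.0684 and 0.254).

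The probe sets for Bacillus transcripts, used on these arrays as spike-in controls, were high on 3 arrays, one of each SKBR3-labelled group and ZR75-1 HSD17B14 array 2, and low on the other 5. The interferon median in the SKBR3-labelled cells was 1.48 within the high arrays and 1.55 within the low ones, each 1 array against 1. With the spike-in level as a block it was 1.57. The block could not move this value, since both SKBR3-labelled groups hold 1 high and 1 low array. In ZR75-1 the interferon median was 0.47 within the low arrays and 0.37 with the block, and the high arrays of that line hold no control. Without SKBR3-labelled control 2 the count of calls was 125, and without HSD17B14 array 1 it was 40.

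**Figure D2:**
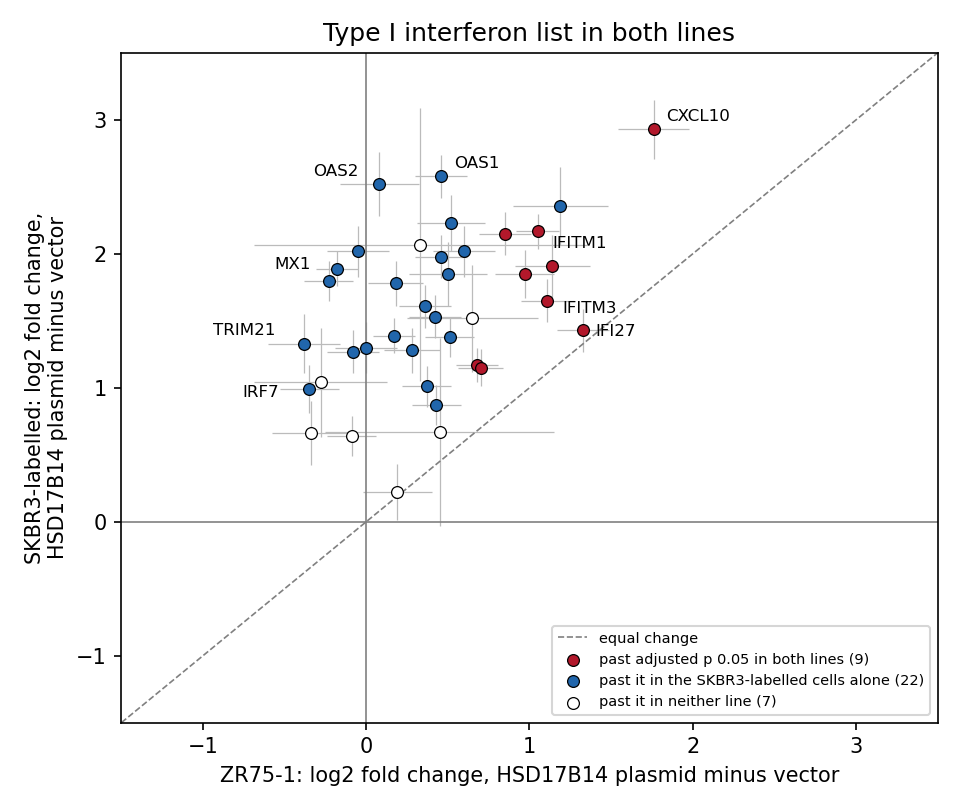
Log2 change with the plasmid in ZR75-1 (x axis) against the SKBR3-labelled cells (y axis) for 38 type I interferon response genes, with bars for the standard error. Red points passed adjusted p = 0.05 in both lines (9 genes), blue points in the SKBR3-labelled cells alone (22) and white points in neither (7).

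Averaged over both lines, with 4 arrays per arm, 76 probe sets were called higher and 18 lower. This upward majority held among the calls only. At an unadjusted limma p under 0.05, 427 were higher and 458 lower, and the median change of all probe sets was -0.02. CXCL10 rose 2.35 ± 0.16 (adjusted p = 1.64e-05) and IFITM1 1.61 ± 0.09 (adjusted p = 9.85e-06), beside OAS1 at 1.52 ± 0.11, MX2 at 1.77 ± 0.20, RTP4 at 1.68 ± 0.19 and TNFSF10 at 1.59 ± 0.21. The inflammatory genes CFB (3.25 ± 0.47), CXCL2 (2.51 ± 0.40) and IL6 (1.60 ± 0.22) passed too, as did HSD17B14 (6.10 ± 0.55) and CST4 (1.82 ± 0.40). The fitted sizes of CFB, CXCL2, HSD17B14 and CST4 depend on groups under the floor, and for IL6 1 of the ZR75-1 controls lay under it (12.6). Among genes of mitosis, PLK1 fell by 1.12 ± 0.16 (adjusted p = 0.00343), CDC20 by 0.73 ± 0.11 (adjusted p = 0.00464), the spindle protein TACC3 by 0.67 ± 0.14, and UBE2S, a ubiquitin-conjugating enzyme of mitosis, by 0.65 ± 0.14. UCP2 fell by 1.19 ± 0.12, USF2 by 1.73 ± 0.37, RAB1B by 0.64 ± 0.14, the gluconeogenic enzyme FBP1 by 0.63 ± 0.13, the chromatin protein HMGA1 by 0.62 ± 0.12 and CCNI by 0.61 ± 0.10. The fitted size for USF2 also depends on a group under the floor, the ZR75-1 HSD17B14 arrays. The count of 94 was 221 without SKBR3-labelled control 2 and 58 without SKBR3-labelled HSD17B14 array 2.

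By list, 29 of 38 interferon genes rose on average, 0 fell and 33 rose when adjusted over the list alone (median 0.98, camera adjusted p = 3.32e-57, and adjusted p = 0.00402 with an estimated correlation). Of 35 G2/M genes 3 fell, also when adjusted over the list alone (median -0.14, camera adjusted p = 0.0345, and adjusted p = 0.245 with an estimated correlation). Histones H1-2 (0.65 ± 0.10), H2BC9 (1.03 ± 0.18) and H2BC12 (0.56 ± 0.11) rose, 3 of 21 and 4 when adjusted over the list alone (median 0.13, camera adjusted p = 0.0361, and adjusted p = 0.245 with an estimated correlation). The NF-kB targets had 2 of 25 higher, also over the list alone (median 0.23). The fatty acid metabolism list had FASN lower at -0.86 ± 0.18, 1 of 26 and 2 over the list alone (median -0.15). Both lists had camera adjusted p = 0.0361 and adjusted p = 0.245 with an estimated correlation. PSME1, a proteasome activator subunit, rose by 0.51 ± 0.09, 1 of 28 proteasome genes and also 1 adjusted over the list alone (median 0.06, camera adjusted p = 0.0361, and adjusted p = 0.539 with an estimated correlation). Ribosomal protein genes had 0 of 42 called by limma either way, 4 lower at an unadjusted p under 0.05 and a median of -0.12, which turned to 0.02 with median centring (camera adjusted p = 0.0361, and adjusted p = 0.929 with an estimated correlation). With median centring the G2/M, NF-kB, fatty acid, histone and ribosomal lists did not pass (camera adjusted p from 0.146 to 0.601), and with quantile normalization the proteasome and ribosomal lists did not (0.355 and 0.761). Estrogen response genes went both ways, with IGFBP4 at -0.76 ± 0.12 and SERPINA3 at 1.00 ± 0.16 (1 higher and 1 lower of 39, 1 and 2 adjusted over the list alone, median 0.01, camera adjusted p = 0.989).

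The difference of the effects tests whether the ER-positive and the ER-negative line answered alike. The HSD17B14 signal with the plasmid was not equal in the lines but higher in the SKBR3-labelled cells. The effects on interferon genes were lower in ZR75-1, where MX1 differed by -2.07 ± 0.18 (adjusted p = 0.00106), LY6E by -2.34 ± 0.24 (adjusted p = 0.00111), and OAS1 by -2.12 ± 0.23 (adjusted p = 0.00142). OAS2 differed by -2.44 ± 0.34, OAS3 by -2.03 ± 0.21, USP18 by -2.07 ± 0.27 and TNFSF10 by -2.27 ± 0.43. Of 38 interferon genes, 16 had a lower effect in ZR75-1 and 0 a higher one, 30 and 0 when adjusted over the list alone (median -1.20, camera adjusted p = 3.92e-32, and adjusted p = 0.0128 with an estimated correlation). The count of 16 was 5 and 4 without ZR75-1 HSD17B14 arrays 1 and 2, 7 without ZR75-1 control 1, and 3 and 5 without SKBR3-labelled HSD17B14 arrays 1 and 2. Other genes with a lower effect in ZR75-1 were IGFBP2 (-5.21 ± 0.50), APOD (-3.18 ± 0.57), the mucin MUC1 (-2.38 ± 0.37), EPHX1 (-2.19 ± 0.34), IGFBP4 (-1.49 ± 0.24), PKM (-1.29 ± 0.24) and TPI1 (-0.96 ± 0.18), and S100A9 differed by -2.14 ± 0.30. For IGFBP2, APOD, MUC1 and S100A9 the SKBR3-labelled controls lay under the floor. In the other direction 4 genes passed: CSRP2 (3.76 ± 0.53, with ZR75-1 under the floor), the ribosomal protein gene RPL38 (1.67 ± 0.27), NDC80 (1.27 ± 0.24) and ODC1 (1.00 ± 0.19). In all, 4 probe sets had the higher signed log2 effect in ZR75-1 and 35 in the SKBR3-labelled cells, but this split rests on both ZR75-1 control arrays, since it was 13 and 12 without control 1 and 17 and 22 without control 2.

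Genes next in order that did not pass were TFRC (0.92 ± 0.18), ATF3 (1.18 ± 0.24), UROD (1.10 ± 0.23), HSD17B11 (2.76 ± 0.59, with ZR75-1 under the floor), NDUFA6 (0.87 ± 0.19) and BIRC2 (1.06 ± 0.24), with adjusted p from 0.0533 to 0.088. Ribosomal protein genes differed with a median of 0.45 (1 of 42 larger in ZR75-1, also adjusted over the list alone, camera adjusted p = 1.7e-11, and adjusted p = 0.497 with an estimated correlation). Proteasome genes differed with a median of 0.39 (0 of 28 called by limma, 9 larger at an unadjusted p under 0.05, 6 adjusted over the list alone, camera adjusted p = 3.57e-06, and adjusted p = 0.356 with an estimated correlation). Oxidative phosphorylation genes differed by 0.24 (0 of 40 called by limma, 8 larger and 1 smaller at an unadjusted p under 0.05, 1 larger adjusted over the list alone, camera adjusted p = 1.85e-04, and adjusted p = 0.497 with an estimated correlation). G2/M genes differed by 0.13 (1 of 35 larger, 3 adjusted over the list alone, camera adjusted p = 0.0209, and adjusted p = 0.426 with an estimated correlation). After quantile normalization these medians were 0.14 for ribosomal protein, 0.25 for proteasome, 0.15 for oxidative phosphorylation and 0.16 for G2/M genes (camera adjusted p = 0.0459, 0.00691, 0.0278 and 0.0179). Among 39 estrogen response genes 1 differed, IGFBP4, and 4 when adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.204). The count of 39 was 7 with median centring and 5 without SKBR3-labelled HSD17B14 array 1, and with the actin ratio as a covariate limma passed 0, with 241 at an unadjusted p under 0.05.

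A small group of genes rose in both lines. These 12 were HSD17B14, CFB, CXCL10, HERC5, IFI27, IFI6, IFIT3, IFITM1, IFITM3, ISG20, UBE2L6 and XAF1, against 0.43 probe sets for independent lists (Fisher's exact test, p = 4.67e-15). HSD17B14 among them is the transfected gene. The test takes probe sets as independent, but interferon genes moved together and the calls of both lines use the same pooled spread. Its p-value may therefore be far too small. The genes that fell shared 0, with 0.024 for independent lists (Fisher's exact test, p = 1). Across all tested probe sets the effects of the lines correlated weakly, with Pearson's r of 0.08 and Spearman's rho of 0.06 across genes, and 51.8% had the same sign. Of the 62 probe sets called in the SKBR3-labelled cells 47 had the same sign in ZR75-1, of the 95 called in ZR75-1 56 had the same sign in the other line, and 0 were called with opposite signs.

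The vector controls show how the lines differ 48 h after transfection with the empty vector. ZR75-1 held the luminal genes. SCGB2A2, or mammaglobin, was at least 174-fold higher than in the SKBR3-labelled controls (adjusted p = 4.91e-06), and S100A8 at least 131-fold (adjusted p = 3.72e-06). CRIP1 was higher by at least 95.6-fold (adjusted p = 2.12e-08) and MUC1 by at least 67.1-fold (adjusted p = 1.26e-08). S100A9 was at least 65.4-fold higher, IGFBP2 40.3-fold, SCGB1D2 33.6-fold, AZGP1 32-fold, TFAP2B 19.2-fold and S100A7 8.25-fold, all as lower bounds. In the SKBR3-labelled controls mesenchymal genes were higher. VIM, the intermediate filament vimentin, had signals of 5325.8 and 4637.6 against 6.9 and 23.2 (log2 -8.62 ± 1.06, adjusted p = 5.82e-05), and the receptor kinase AXL was at least 31.3-fold higher (adjusted p = 3.15e-06). Lower bounds for the others were 50.9-fold for IGFBP7, 45.0-fold for PRSS23, 36.9-fold for PHLDA1, 30.6-fold for the proteoglycan SRGN, 21.3-fold for HSD17B11, 20.2-fold for tissue factor F3, 16.5-fold for CSRP2 and 9.55-fold for the chemokine CXCL8. Of 6251 probe sets 1224 were higher and 1292 lower in ZR75-1, and 571 passed in all with the actin ratio as a covariate, which was 2.03 and 2.02 on the ZR75-1 controls and 3.60 and 3.0 on the SKBR3-labelled ones.

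By list, 19 of 20 luminal markers were higher in ZR75-1 and 0 lower, also when adjusted over the list alone (median 2.71, camera adjusted p = 3.89e-14, and adjusted p = 0.0255 with an estimated correlation). The same held for 27 of 39 estrogen response genes with 3 lower, 28 and 3 adjusted over the list alone (median 1.79, camera adjusted p = 1.12e-08, and adjusted p = 0.0255 with an estimated correlation). ESR1, the estrogen receptor, was higher by 3.86 ± 0.34 and its target TFF1 by 1.03 ± 0.14. Of 12 basal and mesenchymal markers 9 were higher in the SKBR3-labelled controls and 2 lower, also when adjusted over the list alone (median -4.02, camera adjusted p = 3.48e-04, and adjusted p = 0.146 with an estimated correlation). ERBB2 was higher in ZR75-1 by 2.59 ± 0.31 (adjusted p = 4.4e-05), and the HER2 list had 4 of 15 higher and 3 lower, also over the list alone (median -0.12, camera adjusted p = 0.813). With the vector alone, 23 of 38 interferon genes were higher in ZR75-1 and 7 lower, 23 and 8 adjusted over the list alone (median 0.91, camera adjusted p = 6.9e-05, and adjusted p = 0.129 with an estimated correlation). G2/M genes were lower in ZR75-1 in 17 of 35 cases and higher in 4, 18 and 4 adjusted over the list alone (median -0.62, camera adjusted p = 5.68e-04, and adjusted p = 0.129 with an estimated correlation).

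**Figure D3:**
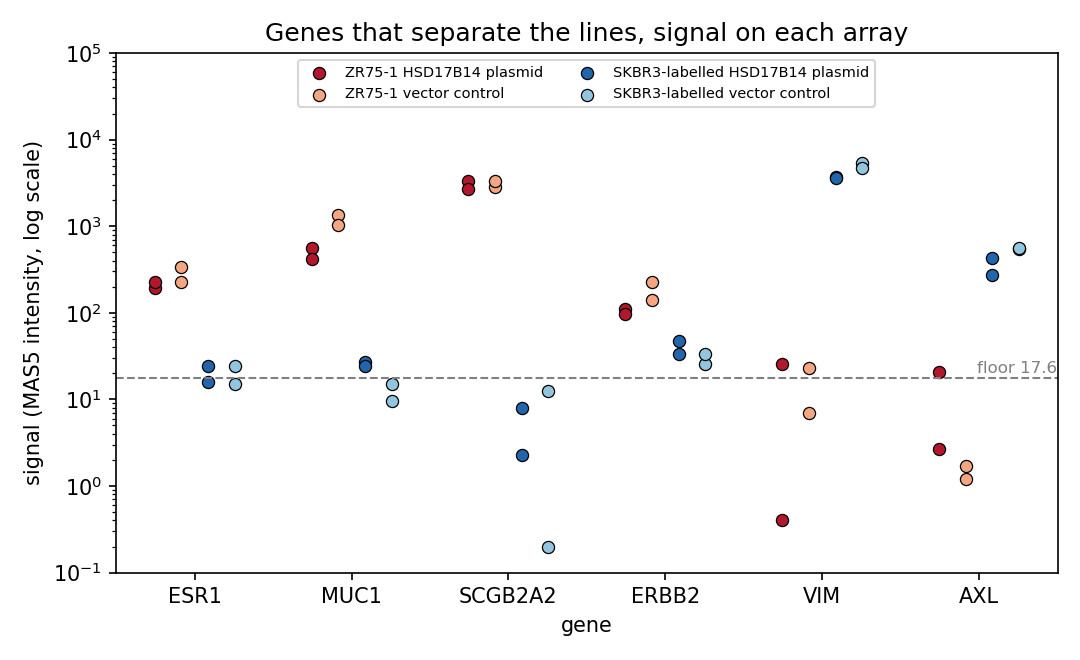
Signal per array on a log axis for ESR1, MUC1, SCGB2A2, ERBB2, VIM and AXL in the 4 groups of 2 arrays, with a dashed line at the common floor of 17.6. ESR1, MUC1, SCGB2A2 and ERBB2 were higher on the ZR75-1 control arrays, and VIM and AXL on the SKBR3-labelled control arrays.

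The remaining steroid-related genes did not pass in either line. ESR1 had log2 changes of -0.41 ± 0.34 (adjusted p = 0.565) in ZR75-1 and 0.06 (adjusted p = 0.992) in the SKBR3-labelled cells. TFF1 had 0.39 ± 0.14 (adjusted p = 0.159) and 0.13 (adjusted p = 0.918), and ERBB2 -0.79 ± 0.31 (adjusted p = 0.203) and 0.42 (adjusted p = 0.823). HSD17B12 had values of 0.29 ± 0.13 and -0.36, HSD17B4 -0.09 ± 0.17 and 0.09, and HSD17B10 0.03 ± 0.15 and -0.13. HSD17B7 had -0.11 ± 0.21 and -0.07, and HSD17B1 in ZR75-1 -0.13 ± 0.90, all with adjusted p from 0.284 to 0.984. HSD17B11 had -0.20 (adjusted p = 0.975) in the SKBR3-labelled cells, and HSD17B14 in the vector controls did not pass as different between lines (adjusted p = 0.303), with the SKBR3-labelled ones under the floor. HSD17B2, HSD17B3, HSD17B6 and PGR, the progesterone receptor, lay below the filter, and GREB1 has no probe set with a single symbol here. The 18 tested sex steroid enzymes had 2 genes higher in ZR75-1, HSD17B14 and HSD17B11, also when adjusted over the list alone, with a median of -0.07 against a mean of 0.37 and an upward test direction (camera adjusted p = 0.419). Of the marker lists for other cell types, the 9 fibroblast and 8 leukocyte genes had 0 members called by limma in either line, and at an unadjusted p under 0.05 0 fibroblast genes in both lines and 1 and 2 leukocyte genes (camera adjusted p = 0.975 and 0.998 in ZR75-1, 0.661 and 0.875 in the SKBR3-labelled cells). When adjusted over the list alone 1 leukocyte gene was higher in the SKBR3-labelled cells, HLA-DRA at least 1.81-fold, named after its value was seen. The test of change in either direction by fry gave adjusted p = 0.0225 and 0.0904 in ZR75-1 and 0.73 and 3.56e-04 in the SKBR3-labelled cells for the fibroblast and leukocyte lists.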

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

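Of the tests below, all those on ERBB2 and on the interferon genes, and the actin ratio as a covariate and the common floor, were chosen only after the result was seen; those on actin within the array pairs and on scaling, and the splits of the arrays, were written before. The arrays labelled SKBR3 lack the strong ERBB2 signal that HER2 amplification is known to give, and hold high VIM and AXL signals instead. Exchanged labels of the 2 lines are argued against by ESR1, which was 3.86 ± 0.34 higher on the log2 scale in the ZR75-1 controls. An ERBB2 probe set that fails on every array is argued against by its signals of 95.9 to 226 on the ZR75-1 arrays. A failure on the SKBR3-labelled arrays alone cannot be told apart from a low level by its neighbours on the chromosome, which went both ways. Their median was -0.50 (SD 1.5), with GRB7 at least 3.42-fold higher in the ZR75-1 controls and MED1 higher in the SKBR3-labelled ones at -1.48 ± 0.22. This median and SD include GRB7, under the floor in the SKBR3-labelled controls, and PNMT, with 1 of its 4 control signals above it (18.7). It also stays open which line the cells were or whether amplification was lost in them, and no biological explanation was tested.

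The second pattern is the joint rise of interferon genes in the SKBR3-labelled cells, with a difference between lines of -1.20 in the median, and with IFITM1 at -1.12, LY6E at -2.34, OAS1 at -2.12, OAS2 at -2.44, TNFSF10 at -2.27 and USP18 at -2.07. The array batch seen in the Bacillus controls is argued against by medians of 1.48 within the high and 1.55 within the low arrays, each 1 array against 1. RNA of ZR75-1, where 18 of the 38 interferon genes were over 2-fold higher with the vector alone, is argued against. The rise of 10 other genes abundant in ZR75-1 was 2.48% of their ZR75-1 level at the 90th percentile, while that of those 18 interferon genes was 42.2% at the 10th percentile. The controls were given the same amount of vector without the insert, so both arms hold a response to transfected DNA as such. A difference between the plasmids, or in how they were prepared, may cause the rise instead of HSD17B14. As 0 arrays hold cells without plasmid or with another insert, these cannot be told apart. An effect of HSD17B14 that differs between the lines stays open as the biological explanation. The HSD17B14 signal with the plasmid was also higher in the SKBR3-labelled cells than in ZR75-1, and a role of its level was not tested.

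The third pattern is the 49 probe sets that were lower in ZR75-1, where the actin 3'/5' ratio was higher on both HSD17B14 arrays. Their median change was -1.10 as deposited, -1.09 after quantile normalization and -0.89 after median centring, with median standard errors of 0.21, 0.21 and 0.23. Of the 49, 31 and 5 passed after quantile normalization and median centring, the latter moving the median change of all probe sets from -0.04 to 0.16. Both medians lie below the bound of -0.8 set for the test, and all 49 stayed lower at an unadjusted limma p under 0.05 under both scalings. The probe sets were chosen for being lower, and median centring moves all probe sets of a comparison by the same amount. They were thus likely to stay lower, and this outcome cannot decide on scaling as the source. The value of -0.89 also lies within the median standard error of a single probe set from the bound. A part of the change that comes from scaling therefore cannot be told apart, and the number of calls depends on it. With the actin ratio as a covariate their median was -1.14 against -1.10, but the median standard error grew from 0.21 to 0.33, so the calls ended through the error and not the size. Within the SKBR3-labelled pairs, these genes differed with a higher actin ratio by -0.11 in the HSD17B14 arrays and 0.17 in the controls. The GAPDH 3'/5' ratio went the other way, 0.896 and 0.883 with HSD17B14 against 1.084 and 1.039 on the ZR75-1 controls. These ratios thus disagree on RNA integrity. RNA integrity and an effect of HSD17B14 stay open and cannot be told apart in ZR75-1, because both ratios split its arrays as the groups do.

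For the averaged effect, 1 of the 18 splits that keep 2 arrays of each line on each side, the real one, gave as many as 94 probe sets, and the highest of the others gave 39. That split joins the ZR75-1 HSD17B14 arrays with the SKBR3-labelled controls, so it is the difference between the lines and its 39 are those differences. The remaining splits mix the arms within groups, which adds the plasmid's effect to the spread. The splits are thus no measure of chance, and they are too few for a share under 0.05.

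The effects of the lines differed by the test of the difference itself for 39 probe sets. Other genes named that differed, as ZR75-1 minus the SKBR3-labelled cells, were APOD at -3.18, EPHX1 at -2.19, IGFBP2 at -5.21, MUC1 at -2.38, S100A9 at -2.14, CSRP2 at 3.76, NDC80 at 1.27, ODC1 at 1.00 and RPL38 at 1.67. The sizes for APOD, IGFBP2, MUC1, S100A9 and CSRP2 rest on signals under the floor, and with values raised to it they were -1.79, -1.44, -1.82, -1.19 and -0.07 and did not pass (adjusted p from 0.0699 to 0.913). Lists that differed with the preset correlation were G2/M at a median of 0.13, oxidative phosphorylation at 0.24, ribosomal proteins at 0.45 and the proteasome at 0.39. With an estimated correlation, of 0.01, 0.23, 0.57 and 0.07 in that order, these 4 did not pass (camera adjusted p from 0.356 to 0.497). Among the spike-in control probe sets, which stand outside the comparisons, one for lysine was higher with the plasmid in ZR75-1 (19.8 and 39 against 2.5 and 2.3), with the lowest HSD17B14 array at least 1.12-fold higher, since both controls lay under the floor of 17.6. The Bacillus geometric mean was 39.57 and 149.9 on the ZR75-1 HSD17B14 arrays, above the 35.06 and 16.09 of their controls.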

How the results depend on the processing

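The common floor, the spike-in block and the actin covariate, and the scaling, filter and offset alternatives for lists other than quantile normalization, were chosen only after the result was seen. So were median centring, the 60th percentile filter and the offset for the correlation of the effects. SKBR3 stands here for the SKBR3-labelled cells. The interferon list kept its direction and its call in every alternative run and in both lines, apart from the estimated correlation in ZR75-1 (0.43, adjusted p = 0.165). Without 1 array its median ran from 0.29 to 0.47 in ZR75-1, 1.53 to 1.62 in SKBR3, 0.94 to 0.99 averaged and -1.23 to -1.10 for the difference. Its 9 genes called in ZR75-1 were 4 with median centring and with the spike-in block, 0 in limma without the prior and with the actin covariate (12 and 11 at an unadjusted p under 0.05), and 2 to 9 without 1 array. The 31 in SKBR3 and 29 averaged were 5 and 6 without the prior. The 16 for the difference were 4 with median centring, 10 without a filter, 5 with the common floor, 0 in limma without the prior and with the actin covariate (27 and 18 unadjusted), and 3 to 14 without 1 array. Where 1 array is left out, the lone array is assumed to vary like the other groups. Sizes near the floor depend on how it is set, and at least 1 group lay under it for 15 of 95 called probe sets in ZR75-1, 7 of 62 in SKBR3, 8 of 94 averaged, 5 of 39 differences and 485 of 2516 between lines. Except where stated, the cause was not tested.

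The 95 calls in ZR75-1 became 23 with median centring and 62 without a filter. They became 262 with an offset of 32, 13 without the prior, 152 with that line alone, 19 with the spike-in block and 1 with the actin covariate, where the standard errors grew. Leaving out 1 array gave 13 (HSD17B14 array 1) to 134 (SKBR3 control 2), and 46, 43, 23 and 23 without HSD17B14 array 2, control 2 and SKBR3 HSD17B14 arrays 1 and 2. The share that was higher, 48.4%, was 78.3% with median centring, 69.2% without the prior, 34.4% with the offset, 36.3% with the common floor and 30.9% with that line alone, and ran without 1 array from 28.3% (HSD17B14 array 2) to 74% (control 1). The 62 calls in SKBR3 became 9 without the prior and 37 with the actin covariate, and 40 (without HSD17B14 array 1) to 125 (without control 2). Of these the 3 lower were 0 in limma with median centring, without the prior and without HSD17B14 array 1 (91, 165 and 103 unadjusted), 1 with the actin covariate and without control 1 or either ZR75-1 HSD17B14 array, and 11 without control 2. The 94 averaged calls became 165 with the offset and 12 without the prior, with 58 (without SKBR3 HSD17B14 array 2) to 221 (without SKBR3 control 2) and 62 without SKBR3 HSD17B14 array 1. With median centring 73 of 76 were higher (96.1% against 80.9%). The 39 differences became 7 with median centring, 20 without a filter, 67 with the offset, and 0 in limma without the prior and with the actin covariate (623 and 241 at an unadjusted p under 0.05). They ran from 5 (without SKBR3 HSD17B14 array 1) to 42 (without SKBR3 control 2), with 19, 11, 25 and 10 without ZR75-1 HSD17B14 arrays 1 and 2, control 1 and SKBR3 HSD17B14 array 2. The share larger in ZR75-1, 10.3%, was 21.4% with the common floor, 52% and 43.6% without ZR75-1 controls 1 and 2, 18.2% without ZR75-1 HSD17B14 array 2 and 4.76% without SKBR3 control 2. It was 0% in limma without either SKBR3 HSD17B14 array (189 and 192 probe sets unadjusted). The 2516 line differences became 571 with the actin covariate and ran from 2156 to 2492. Median centring moved the median of all changes from -0.04 to 0.16 in ZR75-1 and -0.01 to 0.06 in SKBR3.

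Same-numbered arrays were not taken as pairs, as their deviations correlated at -0.04 in both lines, though in SKBR3 the number coincides with the spike-in level. With the replicate number as a block the calls were 187 in ZR75-1, 75 in SKBR3, 149 averaged and 46 for the difference.

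HSD17B14 in ZR75-1 was 4.30 without the prior, 4.04 with the spike-in block and 4.62 with the actin covariate and did not pass (adjusted p = 0.196, 0.0847 and 0.442). It ran from 2.76 (without control 2) to 5.84 (without control 1). In SKBR3, where the controls lay under the floor, it was 5.30 with the common floor, and the fitted 7.91 did not pass without the prior (adjusted p = 0.0602) and ran from 7.37 to 8.44. The correlation of the effects, 0.08, was 0.14 with the 60th percentile filter and with the offset, 0.15 with the common floor, -0.01 with the spike-in block and -0.19 with the actin covariate, and 0.03 (without SKBR3 control 1) to 0.11 without 1 array, with 0.04 and 0.05 without ZR75-1 HSD17B14 array 2 and control 2. Lists called in ZR75-1 went from 3 to 5 with the common floor and 0 with the estimated correlation, and 2 to 4 without 1 array. In SKBR3 they went from 7 to 4 with median centring and with the offset, 1 with the estimated correlation, and 2 (without control 2) to 11 (without control 1). Averaged they went from 7 to 2 with median centring, 4 with the 60th percentile filter and with the common floor, 3 with the actin covariate, 1 with the estimated correlation and 1 (without SKBR3 control 2) to 6. They were 3, 2 and 2 without ZR75-1 HSD17B14 arrays 1 and 2 and control 1, and 4 and 3 without SKBR3 HSD17B14 arrays 1 and 2. For the difference they went from 5 to 1 with the estimated correlation and 4 to 6 without 1 array.

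Signs turned for values that had not passed: with median centring in ZR75-1 HSD17B4 was 0.11, HSD17B1 0.07 and HSD17B7 0.09, and in SKBR3 HSD17B7 was 0.01. With the actin covariate in SKBR3 HSD17B7 was 0.03 and ESR1 -0.05, and with the spike-in block HSD17B10 in ZR75-1 was 0.00. Without 1 array, HSD17B1 in ZR75-1 ran from -0.51 to 0.24, HSD17B10 from -0.11 to 0.17 and HSD17B7 from -0.34 to 0.11. In SKBR3 HSD17B7 ran from -0.24 to 0.10, ESR1 from -0.30 to 0.41 and HSD17B4 from -0.01 to 0.19. With the common floor ATN1 and HSD17B1 in SKBR3 were 0.00. So was ROR1 in ZR75-1, and the CSRP2 difference was -0.07, both of which had passed. Of the named results, 99 of 114 kept direction and side with quantile normalization, 79 with median centring, 71 with the common floor, 90 with the spike-in block, 68 with the actin covariate and 61 without the prior.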

Other observations

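The tests of this part were all chosen only after the result was seen, as were the genes named here after their values were seen. In the SKBR3-labelled cells the class I heavy chains HLA-B, HLA-C and HLA-G, which present antigen, rose with the plasmid by 1.08 ± 0.14, 1.56 ± 0.15 and 1.24 ± 0.21 on the log2 scale (limma adjusted p = 0.00128, 1.29e-04 and 0.0129). The immunoproteasome subunits PSMB8 and PSMB9 rose by 1.53 ± 0.16 and 2.02 ± 0.19 (adjusted p = 2.68e-04 and 1.29e-04). HLA-E at 0.73 ± 0.17, PSMB10 at 1.05, the transporter TAP2 at 0.47 and B2M at 0.28 ± 0.16 did not pass. In ZR75-1 HLA-B at 0.51, HLA-C at 0.37 and HLA-G at 0.16 did not pass, and the difference between the lines passed for HLA-C (adjusted p = 0.0335).

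RIGI and IFIH1, which are known to sense viral RNA, rose in the SKBR3-labelled cells by 1.61 ± 0.16 (adjusted p = 1.46e-04) and 1.85 ± 0.24 (adjusted p = 0.00135), as did the transcription factor IRF7 by 0.99 ± 0.18 (adjusted p = 0.0209). IFNB1, the gene of interferon beta, had signals of 21.9 and 19.0 against 23.5 and 1.0 there and did not pass (2.07 ± 1.02, adjusted p = 0.598). With the vector alone the median of the 38 interferon genes was 0.91 higher in ZR75-1, with 28 genes higher there and 10 in the SKBR3-labelled cells. With HSD17B14 it was 0.11, with 20 and 18. In ZR75-1 the actin-binding ACTN4 fell by 1.47 ± 0.22, the collagen-modifying PLOD3 by 1.40 ± 0.20, the kinase AKT1 by 1.08 ± 0.23 and lamin LMNA by 1.0 ± 0.16. ID1, an inhibitor of differentiation factors, rose by 1.12 ± 0.22 and S100P by 1.30 ± 0.22.

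Several genes that rose in ZR75-1 from mean signals under the floor were higher in the SKBR3-labelled controls, so traces of RNA from those cells in the ZR75-1 HSD17B14 arrays might be a source. The rise of 10 such genes had a median of 18.2% of the SKBR3-labelled level, while 6 genes abundant in those cells were higher by at most 2.24%, which argues against it for the group. The 10 genes were chosen for having risen, which can raise their share. PRSS23, at 2.24%, belongs to both sets, and for it and HSD17B11, at 1.43%, it stays open. It stays open too for SRPX, at 5.21%, and CSRP2, at 4.85%, which lay under the floor on all ZR75-1 arrays.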
